A study of Mus musculus with 12 samples.

How the data were processed

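Chromatin of C57BL/6 mouse embryos at embryonic day 14.5 was profiled in 12 samples. Whole fetal liver gave ChIP-seq libraries for H3K4me1 (3 libraries), H3K4me2 (2), H3K4me3 (2) and H3K27ac (2) and 1 input DNA library. Proerythroblasts, an early stage of red cell precursors, gave 2 ATAC-seq libraries, in which a transposase cuts open chromatin. In ChIP-seq, formaldehyde-fixed chromatin was sonicated, precipitated with an antibody to the histone mark, size-selected on gels and sequenced, per the labels' protocols. For H3K4me2 the labels name an antibody of 1 supplier among the sample characteristics and of another in the protocol, so which was used is unsettled, and every H3K4me2 value rests on it. The protocol text attached to the ATAC-seq samples describes ChIP, so how the proerythroblasts were isolated, how the transposition was done and whether cut sites were shifted are not given in the sources used here. Of the 12 samples, 11 had a peak list, and the input library entered no comparison.

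The submitters' processing notes name Trimmomatic 0.32, Bowtie 1.0.1, SAMtools and MACS2 and the mouse build mm9. The settings, the MACS2 version and the control used for peak calling are not given in the sources used here. The authors deposited 1 list per library, so peaks were called per library and not on pooled reads. The ChIP lists are in the broad format and the ATAC lists in the narrow format, which also gives a summit. For each peak the authors deposited a fold enrichment over the caller's background, a −log10 p and a −log10 q. The deposited score column equals the whole part of 10 times the −log10 q. The deposited ATAC peak names carry a mark for the removal of mitochondrial reads. Peak values are the authors' own and served to describe each list and to rank or filter peaks within it. Fold enrichments of different marks come from different antibodies at unknown depth and are not comparable as levels. The lists hold no read counts, so sequencing depth is unknown, and a library with fewer peaks can be a shallower library. No test of signal between libraries was therefore made.

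The files' coordinates run past the gene table supplied for comparison, which is on GRCm38. The last peak on chromosome 1 ends at 197068858 and that on chromosome 7 at 152513024, beyond the highest gene ends in that table (195291439 and 145324059). Positions were therefore kept in mm9, counted from 1, and no gene annotation was used. Tests of gene lists, of proerythroblast accessibility at genes of each cell type list and of distances to transcription start sites had been planned and were not run for this reason. Regions are given by position.

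Peaks on chromosomes 1 to 19, X and Y were used, and 7 peaks on the mitochondrial chromosome were set aside. No filter for repeats or artefact-prone sequence was applied to the lists. A consensus region of a group was a merged stretch of its libraries' peaks that held at least 1 peak of every library. Regions overlapped when they shared at least 1 bp. Replicates were compared by the Jaccard index of covered bases (bases in both libraries divided by bases in either) and by the percentage of peaks shared. For overlap between marks, the percentage of each library's peaks that met a consensus region of the other mark was taken, with its mean and SD over libraries. Chance came from 1000 circular shifts of the consensus regions within each chromosome's span of peaks, 2568.43 Mb in all, with random seed 20. These give a two-sided permutation p of 0.002 at the smallest. Shifts keep the spacing of regions but not the link of peaks to mappable, gene-rich sequence, so the chance level is a low one. Benjamini-Hochberg adjustment covered the 20 ordered pairs. Covered length was compared between groups by a two-sided exact permutation test.

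Accessible sites, meaning consensus ATAC regions, were classed by the marks they overlapped. Broad domains were the 500 widest consensus H3K27ac regions, set against all other consensus H3K27ac regions. The comparison was repeated in each H3K27ac library alone to give an SD. The differences between the widest and the other regions had no test, since regions of a single genome are not replicates. Overlap of the widest H3K27ac regions with the widest regions of other marks was set against the same shifts. Intervals on shares of sites or regions are exact Clopper-Pearson 95% intervals and cover counting error only. Regions named in the results were set by a rule made before the data were examined, and the wide H3K27ac regions without an ATAC site named among the other observations were chosen afterwards. They are the 10 widest consensus H3K27ac regions, the 5 widest consensus H3K4me3 regions, the 5 consensus H3K27ac regions with most ATAC sites and, for each mark and ATAC, the 3 consensus regions of highest mean fold enrichment. The splits by quartile of fold enrichment and by region centre and edge, their repeat at fixed widths, the chance levels for the widest regions of other marks, and the overlap of H3K27ac regions without an ATAC site and H3K4me3 regions without H3K27ac with other marks, set against the same 1000 shifts, were chosen after the data were examined. The labels do not say that libraries came from separate animals, so the spread between them may be technical.

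Alternatives fixed before the data were examined were peaks with −log10 q of at least 5, equal numbers of peaks per library, overlap of at least 50% of the shorter interval, consensus as bases covered in every library, H3K4me1 in at least 2 libraries, ATAC summits alone, 250 or 1000 widest domains, stitching within 12.5 kb, ranking by width times fold enrichment above 1, matching of libraries by number or by the date-like tags in their titles, and leaving out each library in turn. Alternatives used 100 shifts each. The interval code was tested on simulated data. It gave the brute-force answer in 50 of 50 simulated sets, and recovered 22.3% and 61.1% of 10000 simulated sites on H3K27ac regions where 20% and 60% had been planted on top of random placement. Of 40 sets of 2000 randomly placed sites, 0 had p under 0.05. Those sites were spread evenly and tested with fewer shifts than the main results. The check therefore does not cover peaks that cluster in mappable, gene-rich sequence. Analyses used Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and plots matplotlib 3.10.9.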

Results

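The series profiled histone marks in whole mouse fetal liver at embryonic day 14.5, when the liver is the main site of red cell formation, and accessible chromatin in proerythroblasts. Its title concerns hyperacetylated domains and enhancers. H3K4me3 is a mark of active promoters, H3K4me1 of enhancers and promoter flanks, H3K4me2 of both, and H3K27ac of active promoters and enhancers. The comparisons ask how far the marks share sites, which marks lie on proerythroblast accessible sites, and how the widest H3K27ac regions differ from the others. Replicates numbered 3 for H3K4me1 and 2 for each other mark and for ATAC. All values rest on the authors' peak lists, which hold no read counts.

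H3K4me1 and H3K4me2 covered the most sequence and H3K4me3 the least of the histone marks. H3K4me1 peaks covered 109 Mb ± 19.8 (SD, n = 3), H3K4me2 peaks 88.5 Mb ± 5.01 (SD, n = 2), H3K27ac peaks 59.0 Mb ± 8.15 (SD, n = 2) and H3K4me3 peaks 29.6 Mb ± 5.41 (SD, n = 2). Proerythroblast ATAC peaks covered 12.0 Mb ± 3.20 (SD, n = 2). H3K4me3 had 15457 ± 2022 peaks per library and H3K4me1 had 46417 ± 5288. The median fold enrichment over the caller's background averaged 6.77 ± 0.386 in the H3K4me3 lists and 2.61 ± 0.0638 in the H3K4me1 lists, values of different antibodies that do not compare the levels of the marks. The widest single peaks were those of H3K4me1, up to 100892 bp, and 1734 peaks of H3K4me1 replicate 1 exceeded 10 kb against 13 and 38 in the H3K4me3 libraries.

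The covered lengths of every pair of groups were separate except H3K4me1 and H3K4me2, where H3K4me2 replicate 2 (92.1 Mb) exceeded H3K4me1 replicate 2 (91.5 Mb). In the exact permutation test that pair had p = 0.4. Each other pair had the smallest p its design allows, 0.2 for 3 libraries against 2 and 0.333 for 2 against 2, so no pair of groups can reach 0.05. Restricting to peaks with −log10 q of at least 5 reduced H3K4me1 to 51.9 Mb and H3K27ac to 37.0 Mb, and H3K4me2, at 74.2 Mb, then covered the most.

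Libraries of the same mark resembled each other more than libraries of different marks, with the ATAC pair the least alike among the full lists. The Jaccard index was 0.781 for the H3K4me2 pair, 0.734 for H3K4me3, 0.652 for H3K27ac and 0.577 for ATAC, and averaged 0.650 ± 0.0463 (SD over 3 pairs) for H3K4me1. Between groups the highest values were those of H3K4me1 with H3K4me2, at 0.525 ± 0.0449 (SD over 6 library pairs), of which the highest was 0.588. That is above the ATAC pair and below every pair of the same histone mark. With −log10 q of at least 5 the H3K4me1 libraries were the least alike, at 0.508 against 0.594 for ATAC. Fold enrichment across overlapping peaks, which are not independent replicates, had Spearman correlations from 0.685 to 0.951 within groups. ATAC replicate 1 had 18441 peaks and replicate 2 had 28980. Of the peaks of replicate 1, 92.3% were shared, against 57.6% of those of replicate 2.

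**Figure D1:**
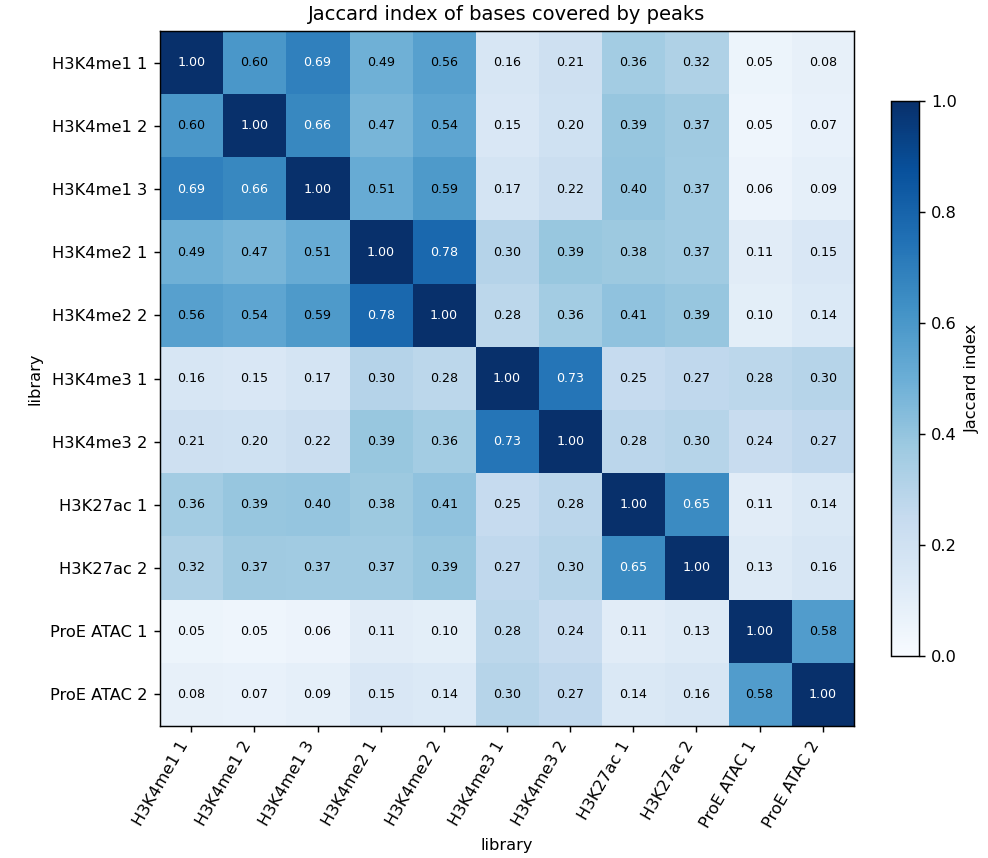
Jaccard index of covered bases for each pair of the 11 libraries (both axes list libraries, colour and printed value give the index). Pairs of the same mark lie between 0.599 and 0.781, the ATAC pair has 0.577, and the highest pair of different groups, 1 library of H3K4me1 with 1 of H3K4me2, has 0.588.

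The marks shared sites far above chance, and H3K4me3 lay almost entirely within H3K4me2. Of H3K4me3 peaks, 99.1% ± 0.307 (SD, n = 2) met a consensus H3K4me2 region, 82.0% ± 2.47 an H3K4me1 region, 72.9% ± 5.31 a proerythroblast ATAC site and 65.6% ± 2.92 an H3K27ac region. The reverse was rarer, as 31.0% ± 0.0627 of H3K4me2 peaks met H3K4me3. H3K27ac peaks met H3K4me1 most often (78.9% ± 6.82, n = 2), then H3K4me2 (69.0% ± 6.30), ATAC (40.5% ± 4.29) and H3K4me3 (36.6% ± 3.90). In the H3K4me1 libraries 33.7% to 44.7% of peaks met H3K27ac (SD 5.69, n = 3), a range that includes the 38.7% ± 0.406 (n = 2) of H3K4me2 peaks.

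In all 20 ordered pairs the overlap exceeded every shift, by 9.34-fold for H3K4me2 peaks in H3K4me1 regions to 43.7-fold for H3K4me3 peaks at ATAC sites (1.67% by chance). Each had a permutation p of 0.002, the smallest that 1000 shifts can give, and an adjusted p of 0.002. Matching libraries by the date-like tags in their titles gave 66.9% of H3K4me3 peaks in H3K27ac for the same tag (1 pair of libraries) and 67.8% for another tag (3 pairs). For H3K27ac peaks in H3K4me2 these were 64.0% and 72.0%. With −log10 q of at least 5, H3K4me1 regions met 25.1% of H3K4me3, 44.7% of H3K27ac, 25.4% of H3K4me2 and 28.4% of ATAC peaks, all above chance. The order for H3K27ac peaks then turned over, with 98.7% in H3K4me2, 89.7% at ATAC sites and 73.0% in H3K4me3, and H3K4me1 last.

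Strong H3K4me3 regions carried H3K27ac and open chromatin nearly without exception, and H3K4me1 was thinned at their centres. From the lowest to the highest quartile of H3K4me3 fold enrichment, 3400 regions each, the share with an H3K27ac peak was 39.2% ± 1.29, 48.7% ± 4.68, 93.8% ± 2.79 and 99.7% ± 0.146 (SD, n = 2). The share with an ATAC peak went from 54.9% ± 9.01 to 99.5% ± 0.25 (n = 2). The regions also widened, from a median of 1116.5 to 2970 bp, and a wider region meets a peak more readily. By share of bases, ATAC peaks took 19.5%, 26.0%, 31.1% and 29.1% from the lowest to the highest quartile. H3K27ac peaks took 42.5%, 38.3%, 68.0% and 80.0%. In the highest quartile an H3K4me1 peak covered 91.7% ± 4.52 of region edges but 50.3% ± 12.9 of centres (SD, n = 3). The centre was lower than the edge in 3 of 3 libraries, by a difference of −41.4 ± 8.48 percentage points. H3K27ac ran the other way there, on 97.0% ± 1.52 of centres and 34.1% ± 6.25 of edges (n = 2), and H3K4me2 covered 99.9% of centres and 98.6% of edges.

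H3K4me3 regions without H3K27ac numbered 4317 of 13600. They were weaker and narrower than the 9283 with it, with a median fold enrichment of 4.39 against 10.3 and a median width of 1259 against 2423 bp. Of those without H3K27ac, 46.8% held an ATAC site (95% interval 45.3 to 48.3), against 93.6% (93.1 to 94.1) of those with it. Consensus H3K4me1 met 53.6% and 98.6% of them.

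Most accessible sites seen in both proerythroblast libraries lay on chromatin that carried both H3K4me3 and H3K27ac in fetal liver. Of 16271 consensus ATAC sites, 62.1% (95% interval 61.3 to 62.8) overlapped both marks, against 1.16% by chance. That interval leaves out the spread of the libraries. All peaks of each ATAC library gave 58.6% and 41.9%, a mean of 50.3% ± 11.8 (SD, n = 2). A further 13.6% (13.1 to 14.1) had H3K4me3 without H3K27ac, 13.7% (13.2 to 14.3) had H3K27ac without H3K4me3, 6.82% (6.43 to 7.21) had H3K4me1 or H3K4me2 only, and 3.81% (3.52 to 4.12) had no mark, against 92.8% by chance. All 4 marks met at 9316 sites, 57.3% of the total. Sites with both H3K4me3 and H3K27ac were the strongest, with a median ATAC fold enrichment of 8.28 ± 0.358 (SD, n = 2). Sites with no mark had 5.34 ± 0.538 and a median width of 326.5 bp against 789 bp.

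Each class differed from chance in the permutation test (p = 0.002, the smallest that the shifts can give). The shares depended on the ATAC library, since peaks seen in 1 library alone were placed differently from shared ones and were mostly those of replicate 2. Of the 1428 peaks of replicate 1 alone, 12.3% had H3K4me3 and H3K27ac, 30.0% had H3K4me1 or H3K4me2 only and 31.6% had no mark. Of the 12282 of replicate 2 alone, 14.1% had H3K4me3 and H3K27ac, 24.1% had H3K27ac without H3K4me3, 28.2% had H3K4me1 or H3K4me2 only and 24.3% had no mark. Without ATAC replicate 1 the unmarked share was therefore 12.5% and the share with H3K4me1 or H3K4me2 only was 15.8%. That with both H3K4me3 and H3K27ac was then 41.9%, no longer most sites. Without replicate 2 the unmarked share was 5.86%, and with equal numbers of peaks per library it was 2.35%. Without H3K4me3 replicate 1 the share with H3K27ac and no H3K4me3 was 8.84%, and with −log10 q of at least 5 the share with both H3K4me3 and H3K27ac was 45.9%, no longer most sites, that with H3K4me3 but no H3K27ac was 22.8% and that with H3K4me1 or H3K4me2 only was 11.3%.

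Around the ATAC summits of peaks shared by both libraries, cover by H3K4me3 and H3K4me2 fell off faster with distance than cover by H3K4me1. Peaks of 1 library alone were left out. From the summit to 2 kb away cover went from 74.9% to 16.1% for H3K4me3 and from 95.3% to 45.0% for H3K4me2. It went from 71.3% to 29.6% for H3K27ac and from 74.8% to 54.6% for H3K4me1. Consensus H3K4me1 regions were wider, with a median of 2806 bp against 2021 bp for H3K4me3 and 1657 bp for H3K4me2. Wider calls alone can slow the fall, and the profile was not recomputed with −log10 q of at least 5. Among sites with H3K4me3, H3K4me1 covered 75.2% of summits, 80.3% of positions at 0.5 kb and 57.7% at 2 kb. Among sites without H3K4me3, H3K4me1 fell from 73.5% at the summit to 44.6% at 2 kb, with no dip at the summit, and H3K27ac from 54.8% to 31.1%. The summits of both ATAC libraries were read at the same sites, so their values differed by an SD of at most 0.275 points in these figures, which is not an error of the marks.

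**Figure D2:**
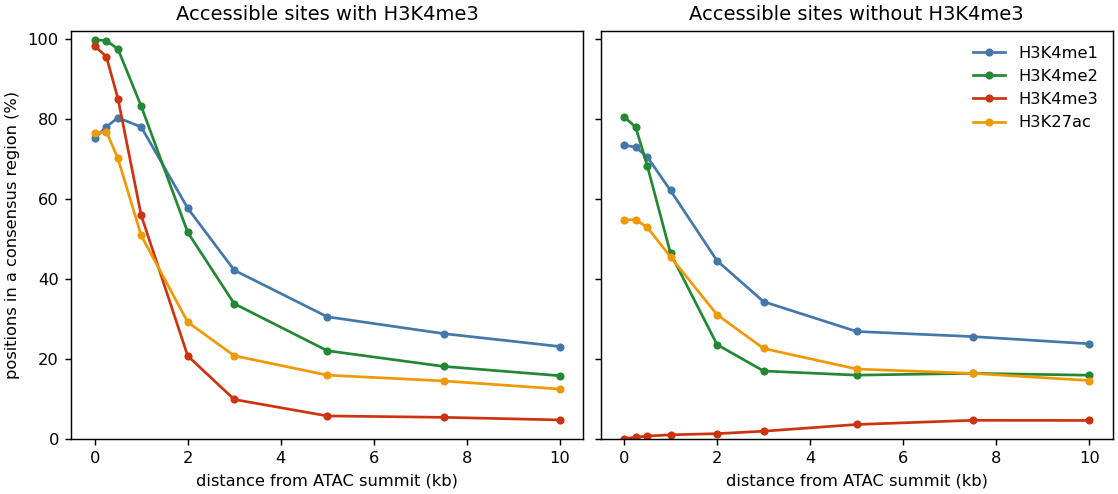
Percentage of positions inside a consensus region of each mark (vertical axis) against distance from the ATAC summit in kb (horizontal axis), as means of the summits of 2 ATAC libraries, for accessible sites with H3K4me3 (left) and without it (right). On the left H3K4me1 is lower at the summit (75.2%) than at 0.5 kb (80.3%), and on the right it is highest at the summit (73.5%).

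In the full peak lists, H3K27ac regions split sharply by H3K4me3 in how often they were open in proerythroblasts. Of the 18238 consensus H3K27ac regions, 9005 overlapped H3K4me3 and 9233 did not. ATAC peaks of a single library lay in 95.5% ± 2.35 (SD over ATAC libraries, n = 2) of the first and in 29.6% ± 14.6 of the others. With consensus ATAC sites the shares were 93.7% (95% interval 93.2 to 94.2) and 18.7% (17.9 to 19.5). With −log10 q of at least 5, 89.7% of H3K27ac peaks met an ATAC site while 73.0% met H3K4me3. The split was therefore less sharp at that threshold, although its size was not recomputed. The gap was narrower in the upper quartiles of H3K27ac fold enrichment, at 73.1 ± 8.04, 76.8 ± 9.30, 52.9 ± 19.4 and 18.7 ± 13.7 points (SD over ATAC libraries, n = 2) from the lowest to the highest, the last being 28.4 points with ATAC replicate 1 and 8.97 with replicate 2. In the lowest quartile 90.6% ± 4.44 of regions with H3K4me3 and 17.5% ± 12.5 of those without it held an ATAC peak, and in the highest quartile 97.8% ± 1.56 of 3576 and 79.1% ± 15.3 of 984. Regions without H3K4me3 also widened across quartiles, from a median of 1389.5 to 4980 bp. Among regions of 2 to 4 kb the gaps were 68.7 ± 9.88, 75.0 ± 12.7, 51.1 ± 19.6 and 29.6 ± 22.2 points. The gap in the highest quartile depended on width. It was 49.5 ± 16.5 points among regions of 1 to 2 kb, of which 54 had no H3K4me3. Among those of 4 to 8 kb, with 428 such regions, it was 13.5 ± 10.6. Both ATAC libraries were read at the same regions, so these SDs do not carry the counting error of 54 regions. In every quartile and both ATAC libraries the share was higher with H3K4me3. The marks come from whole liver and the ATAC peaks from proerythroblasts, so the comparison spans different cell populations.

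**Figure D3:**
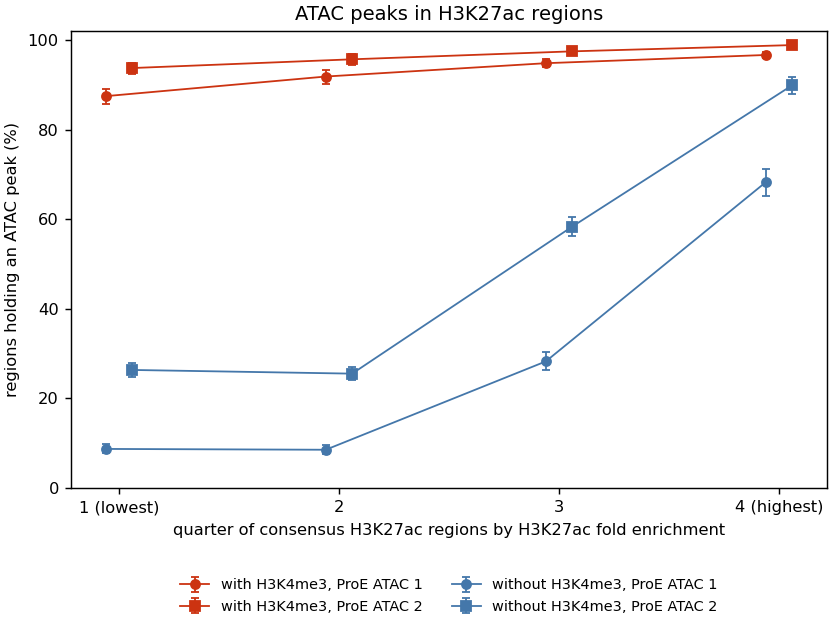
Percentage of consensus H3K27ac regions holding an ATAC peak (vertical axis) by quartile of H3K27ac fold enrichment (horizontal axis), for regions with and without H3K4me3 and for each of 2 ATAC libraries, with exact 95% binomial intervals as bars. Regions with H3K4me3 stay near the top throughout, and those without it rise from a mean of 17.5% to 79.1%.

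The 500 widest H3K27ac regions, from 13.938 to 74.472 kb, held an accessible site in nearly every case, most held at least 2, and they had less of their length under H3K4me3. A consensus ATAC site lay in 94.2% of them against 54.6% of the 17738 others, and at least 2 sites in 66.4% against 7.44%. They held 2.18 sites per region against 0.634, a ratio of 3.45. Per 10 kb of region the order was the opposite, with 1.02 against 2.17 sites, a ratio of 0.470. A region with 1 site has more sites per 10 kb the narrower it is, so this order can follow from width alone. H3K4me1 regions per 10 kb were likewise fewer in the widest, at 0.739 against 3.45. H3K4me3 was met by 82.4% of the widest and 48.4% of the others, but took 22.2% of their bases against 36.0%, while H3K4me1 took 89.6% against 83.9%. Among the widest, 56.4% (95% interval 51.9 to 60.8) overlapped 1 of the 500 widest H3K4me1 regions, against 1.03% by chance, and 26.8% (23.0 to 30.9) overlapped 1 of the 500 widest H3K4me3 regions, against 0.577% by chance (permutation p = 0.002 for each, the smallest that the shifts can give). By share of bases, the widest H3K4me1 regions took 56.3% of the widest H3K27ac regions and 8.00% of the others, and the widest H3K4me3 regions 10.9% and 4.02%.

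Repeated in each H3K27ac library alone, the differences in ATAC sites and in bases under H3K4me3 and H3K4me1 exceeded the spread of the H3K27ac libraries. The consensus regions of ATAC and the other marks were held fixed, so these SDs hold no spread of those libraries. In regions of 16 kb or more, ATAC replicate 1 had 2.55 peaks per region and replicate 2 had 3.48. ATAC sites lay in 95.0% ± 0.283 of the widest and 39.4% ± 4.23 of the other regions (SD, n = 2), with 2.09 ± 0.0509 against 0.451 ± 0.0456 sites per region and 1.14 ± 0.0713 against 2.32 ± 0.279 per 10 kb. The difference in bases under H3K4me3 was −10.6 ± 1.06 points and that under H3K4me1 was 10.8 ± 2.50 points. H3K4me2 had no settled direction, at 70.2% against 73.8% of bases in the consensus and a difference of 2.76 ± 2.37 points in the libraries alone. The H3K4me1 difference, 5.71 points in the consensus, was 9.07 without H3K27ac replicate 1, 12.6 without replicate 2, 13.7 over bases covered in every library and 33.4 with −log10 q of at least 5, and turned to −5.05 points when regions within 12.5 kb were stitched. The last threshold also moved the H3K4me3 difference from −13.7 to −31.8 points and the ratio of sites per region from 3.45 to 1.99.

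**Figure D4:**
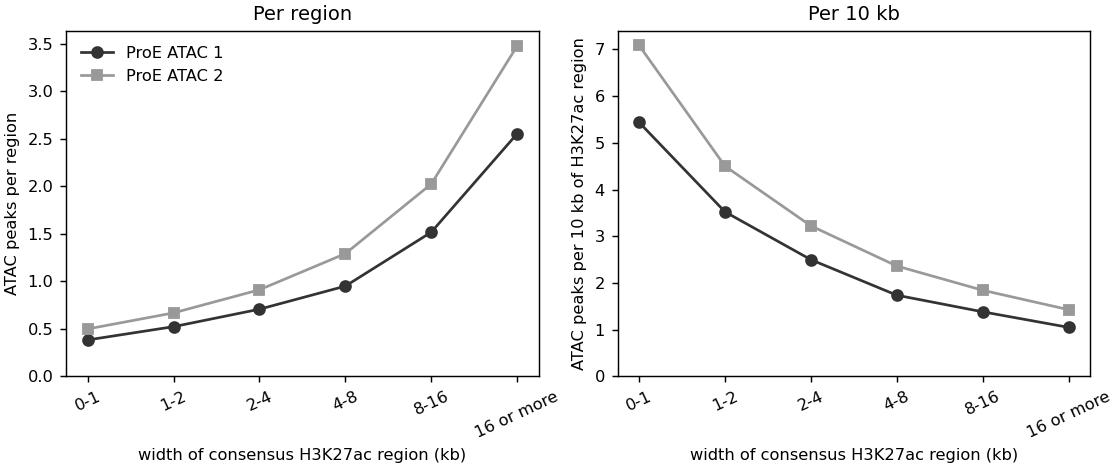
ATAC peaks per consensus H3K27ac region (left) and per 10 kb of region (right) by region width in kb, 1 line for each of 2 ATAC libraries. In ATAC replicate 1 peaks per region go from 0.382 in regions under 1 kb to 2.55 in the 343 regions of 16 kb or more, and peaks per 10 kb go from 5.44 to 1.05. The fall per 10 kb can follow from width alone.

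The widest consensus H3K27ac region, chromosome 13 from 23617565 to 23692036 (74.472 kb, mm9), also held the most ATAC sites, 18, along with 8 H3K4me3 regions over 66.6% of its length. Its mean H3K27ac fold enrichment was 8.34 ± 1.35 (SD, n = 2). A neighbour, chromosome 13 from 23826867 to 23858964, held 6 ATAC sites and had a fold enrichment of 11.3 ± 2.18. The other 9 of the 10 widest held 1 to 5 ATAC sites each, with H3K4me3 over 1.66% to 15.6% of their length. Chromosome 4 from 33521682 to 33586674 (64.993 kb) held 3 ATAC sites, with H3K4me3 over 1.66% of its length. Chromosome 15 from 35366715 to 35430187 (63.473 kb) held 1 site and 5.86%. Chromosome 11 from 11584151 to 11644700 (60.55 kb) held 5 sites and 14.5%, and chromosome 4 from 130237988 to 130298332 (60.345 kb) held 3 sites and 3.25%. The remaining 5 of the 10 widest lay on chromosomes 6, 3, 18, 16 and 3. H3K27ac replicate 2 split 9 of the 10 into at least 3 peaks.

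The highest H3K27ac fold enrichment, 13.4 ± 2.46 (SD, n = 2), was in the region of chromosome 7 from 110987488 to 111030867 (43.38 kb). It held 5 ATAC sites in each library and was covered by H3K4me1 throughout (fold enrichment 6.36 ± 1.04, n = 3) and by H3K4me3 over 19.9%. The H3K4me2 region of highest fold enrichment, 12.4 ± 0.895 (n = 2), lay nearby at 110962108 to 110965737. Regions with 6 ATAC sites also lay on chromosome 11 from 32134929 to 32178124, chromosome 18 from 32692640 to 32722282 and chromosome 16 from 8743056 to 8770075. The strongest H3K27ac region without consensus H3K4me3 among those named was chromosome 15 from 6006820 to 6015345, at 10.7 ± 2.22 with 1 ATAC site.

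**Figure D5:**
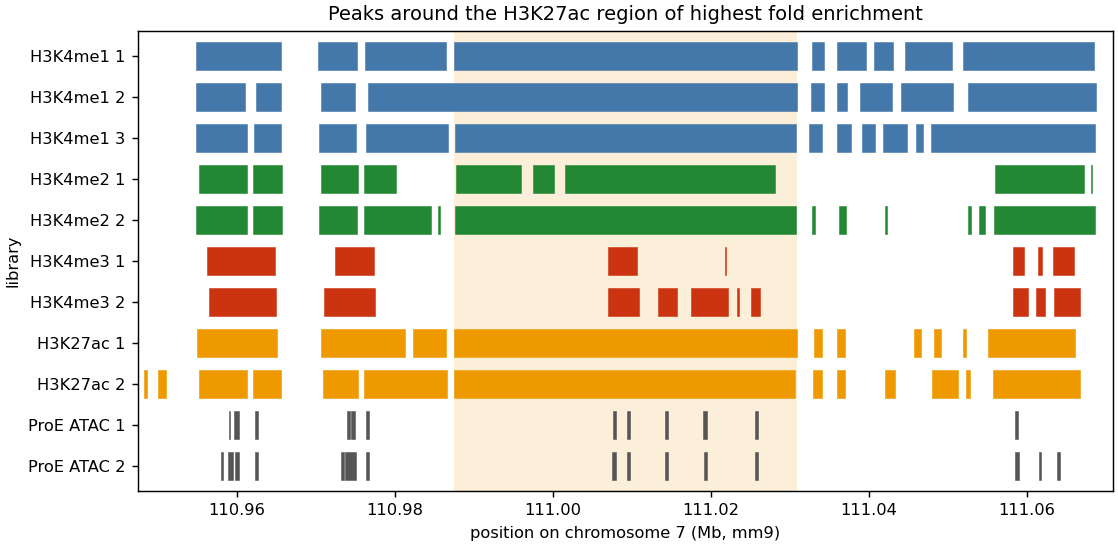
Peaks of each of the 11 libraries (rows) along chromosome 7 (horizontal axis, Mb, mm9) around the consensus H3K27ac region from 110987488 to 111030867, which is shaded. Both H3K27ac libraries cover the shaded stretch with 1 peak each, and both ATAC libraries have 5 narrow peaks within it.

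The strongest H3K4me3 region, chromosome 10 from 115253190 to 115257331, had a fold enrichment of 28.7 ± 8.71 (SD, n = 2), with H3K27ac over 96.9% of its length and 1 ATAC site. The next were on chromosome 7 from 142902842 to 142909351 (27.1 ± 4.55) and chromosome 16 from 32608127 to 32615600 (23.7 ± 4.84). The widest H3K4me3 region, chromosome 8 from 24143686 to 24170408 (26.723 kb), lay wholly within H3K27ac and H3K4me2 and held 2 ATAC sites, as did each of the 5 widest. The strongest H3K4me1 region, chromosome 1 from 153055458 to 153056558 (7.06 ± 0.843, n = 3), had neither H3K4me3 nor an ATAC site. The strongest ATAC site, chromosome 3 from 5860528 to 5860870, reached 30.3 ± 2.91 (n = 2) and overlapped no mark. The next ATAC sites, chromosome 9 from 35112716 to 35113182 (27.1 ± 0.30) and chromosome 6 from 103598970 to 103599331 (24.5 ± 0.214), overlapped a consensus region of H3K4me3 alone, 521 bp and 434 bp wide, with fold enrichments of 2.17 ± 0.434 and 3.49 ± 0.737. The chromosome 6 site also met a peak of H3K27ac replicate 1 (1.80) and of H3K4me1 replicates 1 (1.66) and 2 (1.75). Those 3 peaks were 374, 363 and 398 bp wide, close to the 362 bp of the ATAC site. No filter for artefact-prone sequence was applied, so an artefact shared by libraries is not excluded at these strongest ATAC sites.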

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

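The tests of weak ATAC calls and of calls placed by chance were chosen after the result had been seen. So were the counts among the strongest ATAC sites and the values at fixed widths. The other tests of explanations were set before.

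The widest H3K27ac regions differed from the other H3K27ac regions in opposite directions for different marks, in every library of each mark. The bases covered were higher in the widest by 7.81 percentage points for H3K4me1 (SD 2.51, n = 3). The difference was −4.68 points for H3K4me2 (SD 2.73, n = 2), −14.1 for H3K4me3 (SD 1.13, n = 2) and −9.27 for ATAC (SD 1.39, n = 2). The H3K4me1 and H3K4me2 directions depend on how regions are drawn. The H3K4me1 difference was −5.05 points with regions within 12.5 kb stitched, and the H3K4me2 difference was 2.76 points (SD 2.37, n = 2) with each H3K27ac library used alone. The differences between marks were not tested. A wide region dilutes a narrow peak by its length alone, so the values for H3K4me3 and ATAC describe how the bases are shared out and not how many sites there are.

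Outside the chromosomes compared, H3K4me3 replicate 1 had 4 peaks on the mitochondrial chromosome, which carries no histones. That is above the 3 counts used as a cut-off for flagging, which is not a statistical limit. H3K4me3 replicate 2 had 1 such peak and H3K27ac replicate 2 had 2.

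The first pattern is that 8074 of 18238 consensus H3K27ac regions held no consensus ATAC site. H3K27ac calls placed by chance do not account for most of these, since 79.5% (95% interval 78.6 to 80.4) met H3K4me1, against at most 11.4% in the shifts. The shifts do not keep the link of peaks to mappable sequence, so artefacts shared by ChIP libraries are not excluded. A missed call in 1 ATAC library accounts for some, since 28.9% (27.9 to 29.9) held a peak of 1 library, but that is under the 50% set in advance for it to be the main cause. Weak H3K27ac calls may account for part or most. Of the strongest quartile 9.63% (8.79 to 10.5) lacked a site, against 61.9% and 70.0% of the 2 lowest quartiles. The 10% set in advance lies inside that interval, so this test does not settle it. Stronger regions are also wider. Among regions of 1 to 2 kb without H3K4me3, an ATAC peak lay in 46.3% ± 18.3 of the highest quartile, which held only 54 such regions. In the lowest quartile it lay in 17.5% ± 12.2 (SD over ATAC libraries, n = 2). With H3K4me3 these shares were 95.8% and 93.1%. With −log10 q of at least 5, 89.7% of H3K27ac peaks met an ATAC site, against 40.5% in the full lists. Most H3K27ac peaks without a site were therefore below that threshold. H3K27ac from liver cells other than proerythroblasts remains an open biological explanation, as the number of ATAC libraries of whole liver was 0. Nothing here can separate those cells from low enrichment in all cells, since a mark carried by few cells would also be weak.

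The second pattern is that 4317 of 13600 consensus H3K4me3 regions lacked consensus H3K27ac. H3K4me3 calls placed by chance do not account for most of these, since 98.5% (95% interval 98.1 to 98.8) met H3K4me2, against at most 8.59% in the shifts, and 46.8% (45.3 to 48.3) held an ATAC site, against at most 4.05%. Artefacts shared between libraries are again not excluded by the shifts. Of those in the weakest quartile of H3K4me3 fold enrichment, 97.0% met H3K4me2 and 26.4% held an ATAC site. Peaks missed in 1 H3K27ac library explain little of it, since 13.3% (12.3 to 14.3) of these regions held a peak of 1 library. Low H3K4me3 enrichment goes with the lack of H3K27ac, as 0.5% (0.292 to 0.799) of the strongest quartile lacked H3K27ac, under the 10% set in advance, against 62.1% of the weakest. Why H3K4me3 is weak at sites that mostly carry H3K4me2 stays open. An antibody to H3K4me3 that also binds H3K4me2 was not tested for, and no biological explanation was tested.

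The third pattern is that 620 of 16271 consensus ATAC sites carried no mark. Peaks missed in single ChIP libraries do not explain most, since 24.7% (95% interval 21.3 to 28.3) of the sites held a peak of a mark in at least 1 library. Weak ATAC calls may account for many, as 0.639% (0.418 to 0.935) of the strongest quartile was unmarked against 8.55% of the weakest. The very strongest sites go the other way, since 3 of the top 20 were unmarked. These sites are few, and no filter for repeats or artefact-prone sequence was applied. Artefacts among them are not excluded, so they do not settle the question. No biological explanation was tested.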

How the results depend on the processing

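All alternatives here were chosen before the data were examined. All 135 recomputed mark overlaps and all 85 recomputed shares of accessible sites stayed on their side of chance, although many shares moved by far more than their SD, such as that of H3K27ac peaks at ATAC sites, which was 89.7% with −log10 q of at least 5. Some of the 85 could not move, such as shares with H3K4me3 when an H3K4me1 or H3K4me2 library was left out. With −log10 q of at least 5, covered length was 51.9 Mb for H3K4me1, 74.2 Mb for H3K4me2 and 37.0 Mb for H3K27ac, the Jaccard index was 0.508 for H3K4me1 and 0.754 for H3K27ac, and 92.3% of H3K27ac peaks were shared. Equal numbers of peaks raised the ATAC Jaccard index to 0.654. Leaving out each H3K4me1 library gave 0.599 to 0.689. Values without a test were judged by whether they moved by over 1 SD, which 31 of 100 did for the widest H3K27ac regions and 3 of 10 for covered length. Many of the 100 could not move, because the setting does not enter the value. Leaving out an H3K4me2 library, for example, left every value for the widest regions unchanged. That lowers the 31 of 100. The SD of 0.283 points for the share with a site raises it, since a change from 94.2% to 94.8% counted as a move. The count is therefore no measure of how far these values depend on the processing. With −log10 q of at least 5, the widest minus the others differed by −31.8 points in H3K4me3 and 33.4 in H3K4me1, the ratio of ATAC sites was 1.99 per region and 0.384 per 10 kb, and 96.2% held a site. Equal numbers gave −14.9 points for H3K4me3 and 93.4% with a site. Bases covered in every library gave −17.3 points for H3K4me3, 13.7 for H3K4me1, 0.431 per 10 kb and 94.8% with a site. Stitching within 12.5 kb gave −15.7 and −5.05 points, the latter reversed, with a ratio of 0.378 per 10 kb and 98.8%; stitched regions include the sequence between peaks. Ranking by signal gave −11.9 points for H3K4me3, 0.509 per 10 kb and 97.2%. The 250 and 1000 widest held a site in 96.0% and 90.2%. Leaving out single libraries gave −14.9 to −9.89 points for H3K4me3, 5.52 to 12.6 for H3K4me1, ratios of ATAC sites of 3.45 to 5.07 per region and 0.470 to 0.511 per 10 kb, and 94.2% to 98.4% with a site. Other causes were not tested.

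The replicate numbers do not pair the libraries, as nothing in the labels ties a number to a shared animal or day. With the replicate block, 67.6% of H3K4me3 peaks met H3K27ac in the library of the same number, against 67.5% in that of another number, and no call changed. Gene list tests, cell type list tests and distances to transcription start sites were not run under any setting. Depth is unknown, so a difference between libraries in peaks called cannot be separated from a difference in depth.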

Other observations

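All values in this part were chosen after the data were examined, and no explanation was tested for them.

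Chromosome X was poor in every mark. Its density of peaks was 0.316 ± 0.0165 (SD, n = 2) of that of the autosomes for H3K27ac, 0.347 ± 0.0164 (n = 3) for H3K4me1, 0.396 ± 0.00221 (n = 2) for H3K4me2 and 0.478 ± 0.0106 (n = 2) for H3K4me3. Proerythroblast ATAC peaks gave 0.383 ± 0.0348 (n = 2). Chromosome 11 was the densest autosome in all 11 libraries. The sex of the embryos is not given in the sources used here.

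Of the 500 widest H3K27ac regions, 29 held no consensus ATAC site, and 8 of these held no peak of either ATAC library. The widest of the 29 was chromosome 19 from 37008579 to 37047218 (38.64 kb, mm9), with H3K4me1 over 97.7% of its length, no consensus H3K4me3 and a peak of ATAC replicate 2 alone. Chromosome 18 from 21392506 to 21419134 (26.629 kb) and chromosome 15 from 34990888 to 35017163 (26.276 kb) followed, again with H3K4me1 (92.9% and 70.4%), no consensus H3K4me3 and a peak of ATAC replicate 2 alone.

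Among the 20 ATAC sites of highest fold enrichment, 3 (15.0%, 95% interval 3.21 to 37.9) had no mark, against 10 (1.00%, 0.481 to 1.83) of the top 1000. In the top 20 the unmarked sites had a median width of 343 bp and the marked ones of 530 bp. The sequence of these sites was not used here. No filter for repeats or artefact-prone sequence was applied, so artefacts among them are not excluded.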
